A study of Mus musculus with 19 samples.

How the data were processed

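RNA was measured by sequencing of polyadenylated RNA in 19 mouse libraries: 9 of sorted alveolar type II (AT2) cells and 10 of lung tissue. Per the labels, control mice carried SpcCreERT2, a Cre recombinase made in cells with an active surfactant protein C promoter and switched on by tamoxifen, with the tdTomato reporter. Mice labelled Etv5KO carried in addition 1 knockout and 1 loxP-flanked allele of Etv5. Per the labels' protocols, all mice received tamoxifen at 100 mg/kg on 5 days followed by a wait of 5 days, and AT2 cells were sorted as EpCAM positive, tdTomato positive, CD45 negative and CD31 negative. The groups hold 4 control and 5 Etv5KO libraries of AT2 cells and 5 control and 5 Etv5KO libraries of lung. The series design names 5 mice per genotype; the fifth control library of AT2 cells was not analysed here. Libraries were numbered in accession order within a group, and the number pairs nothing. The labels do not say which AT2 and lung libraries came from the same mouse, so no pairing was used between them.

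Per the file headers, the deposited count is the number of reads aligned uniquely to each gene model, and a further column holds an RPKM value that the authors divided by a size factor for each sample. Per the submitters' processing notes, GSNAP (version not given) and genome build mm9 were used. The annotation release, the counting tool and whether counting used strand are not given in the sources used here. Reads that align to more than 1 place were left out by the authors, per the file headers, which lowers the counts of genes with near-identical copies. The RPKM column followed the count column exactly once a factor per library and a length per gene were allowed for (largest residual on the log scale 2.84e-14), so it was used only to recover the authors' size factors for an alternative scaling.

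The tables hold 36528 Entrez gene IDs. Of these, 31049 were named from a RefSeq gene table of assembly GRCm38.p6 and 77 from a GENCODE annotation, and 5402 kept their ID. The named genes hold 98.8% of all counts. Since that assembly is not mm9, no coordinates are given and the table was used only for names and for which genes neighbour each other. Counts per library sum to between 14971793 and 28671262. Of 17917 IDs with at least 100 counts, 43 had counts identical to another ID in every library and cannot be told apart from it. No pair of libraries within a group was a duplicate: the chi-square statistic per degree of freedom between replicates ran from 7.30 to 56.9. Xist was at most 3.10 CPM in every library while Y-linked genes were expressed, so a sex covariate was not fitted.

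Each comparison was tested with edgeR 4.0.16 in R 4.3.3 on the counts: genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and the quasi-likelihood F test was two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. AT2 cells and lung were fitted separately, control AT2 cells were compared with control lung in a fit of those 9 libraries, and the difference of the genotype effects was an interaction term over all 19. A gene is said to have risen, fallen or passed when its adjusted p was under the threshold. Values in CPM, the library-size-scaled read counts that edgeR's cpm function gives, are means ± SD over libraries scaled by TMM, within the libraries of the comparison; values for Etv5 per library, for the difference between tissues and for single libraries that stand apart are scaled over all 19. Standard errors of log2 fold changes were derived from the F statistic, and intervals are at 95%.

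Before the data were examined, 29 gene lists were fixed for cell types (AT2, AT1, transitional epithelial, airway secretory, ciliated, basal, endothelial, macrophage, lymphocyte, neutrophil, mesenchymal and red blood cells) and processes (ERK pathway feedback and targets, ETS family, fatty acid and surfactant phospholipid synthesis, cholesterol synthesis, lysosome and lamellar body, cell cycle, interferon response, MHC class II, chemokines and NF-kB response, p53 response, unfolded protein and amino acid stress response, immediate early and dissociation response, NRF2 and glutathione response, YAP and TEAD targets, TGF-beta response, WNT targets, epithelial identity). They were tested with camera in limma 3.58.1, with a preset correlation between genes of 0.01, adjusted over the lists. The same tests were repeated with the correlation estimated for each list and with fry, which asks whether the members move on balance in 1 direction and does not compare them with other genes.

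Genes were named by a rule also fixed before the data were examined: Etv5; the 10 largest rises and 10 largest falls among genes past the threshold, at a mean of at least 5 CPM and with no overlap between the groups' libraries; and up to 4 members with the smallest p of each list past the threshold and of 6 lists named in advance. For the control comparison of AT2 cells with lung and for the difference between tissues, the 5 largest in each direction were named. The difference between tissues was named without the condition on overlap. Symbols of the form Gm or LOC with digits, those ending in Rik and unnamed IDs were counted but not named in this way. Where a list of another cell type passed, its 3 most abundant members were named too. Any other gene named was chosen after its values were seen. The overlap of genes past the threshold was tested with Fisher's exact test on genes tested in both fits.

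Alternatives tried in turn, whose effect the closing section gives, were other scalings (DESeq2 size factors, upper-quartile factors, library size only, the 50 most abundant genes left out), DESeq2 1.42.0, limma-voom with and without sample weights, no or a stricter count filter, 1 surrogate variable from sva 3.50.0, a test against a fold change of 1.2, all 19 libraries in 1 fit, and each library left out in turn. The authors' size factors and a fit without AT2_control 2 and lung_control 1, which stand apart on the principal components, were added after the data were seen. The edgeR tests of genes used the counts, so no pseudocount alternative was run for them. The list tests, principal components and surrogate variable used log2 CPM with a prior count of 2, which was not varied. Other splits of the libraries into groups of the same sizes were drawn 100 times for each comparison, the real one included. Tables and permutation tests used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9.

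The steps were tested on simulated counts with the library sizes of the real libraries. Each gene had its mean over all libraries compared, or over those of each tissue for the difference between tissues. Changed genes were drawn from those with a mean of at least 5 CPM, so recovery below that mean was not tested. With 100 genes changed by 1.5-fold and 100 by 2-fold, the AT2 test recovered 80% and 98% of them among 14818 genes. The lung test recovered 77% and 100% among 16969 genes, the control comparison of AT2 cells with lung 73% and 100% among 16693, and the difference between tissues 28% and 84% among 17584. In the control comparison the simulated tissues differed in the changed genes only. In the real one 12754 of 17118 genes passed, so its recovery in the real data was not tested. A simulated list shifted by 1.5-fold passed in AT2 cells and in lung, and the other lists did not, by camera or fry. Simulated genes were drawn independently, while the median estimated correlation within the real lists was 0.304 in AT2 cells and 0.397 in lung. The simulation therefore does not show how often unchanged lists of correlated genes pass. No label says in words that each library is a separate mouse; if some are not, the p-values measure in part the spread between preparations. Counts are reads without molecular identifiers, so any interval from counts alone covers counting error only.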

Results

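The transcriptomes of sorted AT2 cells, the surfactant-secreting epithelial cells of the alveolus, and of lung tissue were compared between control mice and mice labelled Etv5KO. Etv5 encodes an ETS family transcription factor, and the series asks for its target genes in AT2 cells and in lung. AT2 libraries numbered 4 for controls and 5 for Etv5KO, and lung libraries 5 and 5. Total counts per library lay between 20279607 and 28671262 in control AT2 cells and 17426415 and 26722625 in Etv5KO AT2 cells. They lay between 14971793 and 26989453 in control lung and 20332410 and 22478603 in Etv5KO lung. Sftpc, which encodes surfactant protein C, took 4.98% to 7.71% of all counts in control AT2 libraries and 5.27% to 6.98% in Etv5KO AT2 libraries. Its share was 0.807% to 1.07% in control lung and 0.860% to 1.18% in Etv5KO lung.

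The targeted gene, Etv5 (Entrez Gene 104156), was not lower in the libraries labelled Etv5KO. In AT2 cells it stood at 667 ± 36.1 CPM in controls (SD, n = 4) and 714 ± 58.4 CPM in Etv5KO (SD, n = 5), scaled over all libraries. The log2 fold change was 0.10 (SE 0.08, 95% interval −0.07 to 0.27) and the adjusted p from edgeR was 0.505. In lung it stood at 104 ± 7.20 CPM in controls and 113 ± 10.8 CPM in Etv5KO (SD, n = 5 each), with a log2 fold change of 0.12 (SE 0.08) and an edgeR adjusted p of 0.978. The counts cover whole gene models and do not show which exons the reads came from. The level of Etv5 therefore does not check the genotype labels, and each direction given here compares libraries labelled Etv5KO with libraries labelled control.

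**Figure D1:**
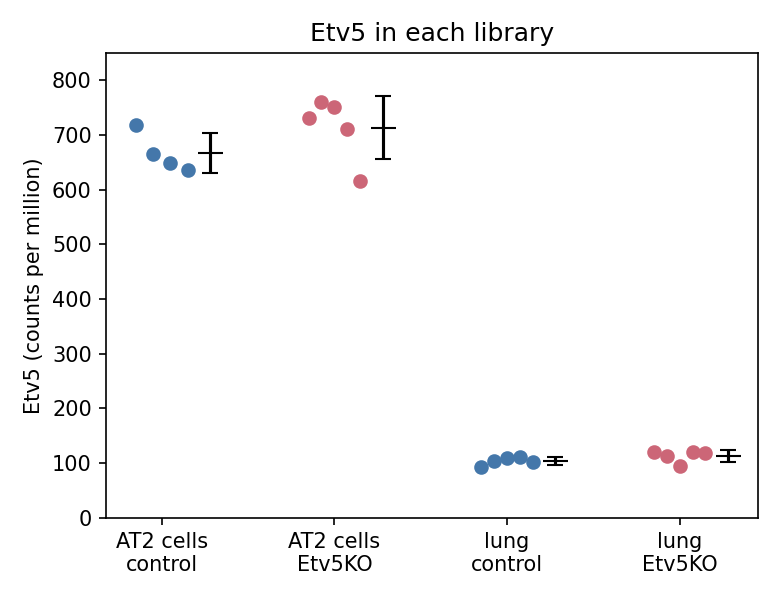
Etv5 in CPM in each of the 19 libraries, scaled over all libraries, with the mean and SD of each group. The AT2 libraries labelled Etv5KO lie between 615 and 761 CPM and the AT2 controls between 636 and 718 CPM; the lung libraries lie between 92.9 and 119.5 CPM.

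In sorted AT2 cells, the furthest falls in the libraries labelled Etv5KO, among genes with a mean of at least 5 CPM, were those of Hes2, Adamts1, Rbp4 and Trf. Trf, the iron carrier transferrin, went from 659 ± 115 to 49.9 ± 10.3 CPM, a log2 fold change of −3.73 (SE 0.17). The secreted metalloprotease Adamts1 went from 183 ± 56.9 to 8.73 ± 2.28 CPM (log2 −4.39) and the plasma retinol carrier Rbp4 from 31.3 ± 8.10 to 1.79 ± 0.484 CPM (log2 −4.11). Hes2, of the Hes family of transcriptional repressors, went from 40.5 ± 19.3 to 0.797 ± 0.406 CPM (log2 −5.71). Acoxl, related to the acyl-CoA oxidases, went from 739.5 ± 92.6 to 118 ± 35.5 CPM (log2 −2.65). The matrix protein gene Tgfbi, the calcium channel gene Trpv6, and Gdpd2, Bex2 and Ppp1r3c completed the 10 largest falls at that mean, with log2 fold changes of −2.91, −2.81, −3.32, −2.62 and −2.33. Values are means ± SD over 4 control and 5 Etv5KO libraries. All Etv5KO libraries lay below all controls for each of these 10 genes, which the rule for naming them required.

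The largest rise at that mean was that of Angpt2, a secreted ligand of the Tie2 receptor, from 1.66 ± 0.591 to 12 ± 1.73 CPM (7.25-fold). Cyp1b1, a cytochrome P450 enzyme, rose from 2.28 ± 0.223 to 15.6 ± 2.16 CPM (6.84-fold). Ncf1, a subunit of the phagocyte NADPH oxidase, rose from 18.7 ± 2.76 to 86.0 ± 11.5 CPM, the chloride channel gene Ano1 from 30.5 ± 4.26 to 118 ± 21.8 CPM, and Emp1 from 24.2 ± 5.26 to 98.4 ± 44.4 CPM. S100a14, Myom2, Ccdc88b, Rasl12 and Entpd3 rose 4.62-fold, 4.68-fold, 4.87-fold, 3.91-fold and 3.89-fold. For AT2 Etv5KO versus control, 1474 of 14939 genes passed with edgeR, 751 higher and 723 lower, and 156 rose and 184 fell by at least 2-fold. With library size as the only scaling the split was 894 higher and 482 lower, and in a test against a fold change of 1.2 the count was 624. Of the 1474 genes, 1318 had no overlap between the groups' libraries. Over all genes tested the share was 12.5%, against 1.59% by chance.

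AT2 marker genes moved apart from each other. Of 20 markers, 6 fell, 1 rose and 13 did not pass. Adjusted over the list alone, 8 fell and 4 rose. Chil1, a chitinase-like protein, fell from 5876 ± 656 to 2852 ± 407 CPM, and Sftpa1, surfactant protein A, from 29116 ± 4462 to 15300.0 ± 2020.3 CPM. Cxcl15 and Dram1 fell with log2 fold changes of −0.66 and −0.46, as did Lpcat1 (−0.46) and Napsa (−0.45), while the cytokine gene Il33 rose by 0.45. Sftpc itself stood at 68315 ± 15113 CPM in controls and 61265 ± 8776 CPM in Etv5KO and did not pass (log2 −0.16, SE 0.19, edgeR adjusted p 0.696). The list was lower than other genes by camera (adjusted p = 0.0346), with an adjusted p of 0.614 with an estimated correlation. The camera call was lost without AT2_Etv5KO 2 or 5 or AT2_control 1, 3 or 4, with an adjusted p of up to 0.117.

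Genes of fatty acid and surfactant phospholipid synthesis mostly fell where they changed. Of 19 members, 7 fell and 1 rose. Adjusted over the list alone, 7 fell and 2 rose. Elovl1, which elongates very long chain fatty acids, fell from 2443 ± 629.6 to 560.1 ± 39.7 CPM (log2 −2.12), the fatty acid binding protein gene Fabp5 from 154 ± 47.0 to 38.6 ± 8.86 CPM, and Acss2, an acetyl-CoA synthetase, from 28 ± 8.48 to 16.2 ± 2.07 CPM. Gpam, which catalyses the first step of glycerolipid synthesis, rose from 619 ± 39.8 to 1330.0 ± 85.5 CPM (2.15-fold). The list was lower by camera (adjusted p = 0.0127), with an adjusted p of 0.546 with an estimated correlation. Of 20 cholesterol synthesis genes, Stard4, a sterol carrier, rose (log2 0.31) and 19 did not pass. The list did not pass by camera (adjusted p = 0.113), but did without AT2_Etv5KO 2 or AT2_control 1 (down to 0.00238).

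Markers of AT1 cells, the flat gas-exchange cells that AT2 cells can give rise to, were higher as a list by camera (adjusted p = 2.5e-05). The adjusted p was 0.263 with an estimated correlation and 0.00819 by fry. Of 20 markers, 8 rose and 1 fell, or 12 and 1 adjusted over the list alone. Clic5 rose from 140.0 ± 8.28 to 271 ± 33.6 CPM, Emp2 from 661 ± 21.1 to 996 ± 39.2 CPM, Timp3 from 144 ± 19.6 to 254 ± 42.7 CPM and Gprc5a from 576 ± 40.6 to 749 ± 58.2 CPM. Ager, the most abundant marker in the list, rose from 1950.3 ± 241 to 2618 ± 239 CPM, while the water channel gene Aqp5 fell with a log2 fold change of −0.30. With TMM scaling, Ager, Gprc5a and Aqp5 were higher in control AT2 cells than in control lung, so their changes alone do not mark AT1 cells here. Of 16 transitional epithelial markers, 6 rose and 2 fell, or 9 and 3 adjusted over the list alone. Lgals3 (2.01-fold) and Krt7 (1.54-fold) were among those that rose, and Nupr1, a stress-response gene (from 159.7 ± 39.9 to 33.6 ± 11.2 CPM), and Clu (log2 −0.70) were those that fell. The transitional list had a camera adjusted p of 0.00611, and an adjusted p of 0.546 with an estimated correlation.

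Airway secretory markers were also higher as a list by camera (adjusted p = 2.36e-05, and an adjusted p of 0.546 with an estimated correlation). Of 12 markers, 4 rose and 8 did not pass, or 7 rose adjusted over the list alone. Cyp2f2, a cytochrome P450 of club cells, rose from 99.2 ± 27.5 to 314 ± 16.7 CPM (3.16-fold), Bpifb1 from 1.69 ± 0.687 to 3.93 ± 0.870 CPM, the mucin gene Muc5b from 0.619 ± 0.240 to 1.59 ± 0.503 CPM and Hp, haptoglobin, from 1224 ± 249 to 1946 ± 321 CPM. Hp is among the 3 most abundant members. Hp, Bpifb1, Cbr2, Bpifa1 and Scgb3a1 were higher in control AT2 cells than in control lung, so their changes alone do not mark airway cells here. Cbr2 stood at 3815 ± 530.2 CPM in controls and 5117 ± 729 CPM in Etv5KO, and Scgb1a1, the secretoglobin of club cells, at 353 ± 137 CPM in controls and 401 ± 120.0 CPM in Etv5KO (edgeR adjusted p 0.0765 and 0.785). Of 7 ciliated cell markers, Tppp3 rose from 83.8 ± 5.72 to 134 ± 21.6 CPM and Dynlrb2 from 14.5 ± 2.06 to 23.0 ± 4.78 CPM, and 3 rose adjusted over the list alone. Foxj1, the transcription factor of ciliated cells, stood at 2.44 ± 0.458 CPM in controls and 2.38 ± 0.295 CPM in Etv5KO, Rsph1 at 0.702 ± 0.248 CPM in controls and 1.18 ± 0.266 CPM in Etv5KO and Cdhr3 at 0.570 ± 0.0771 CPM in controls and 0.694 ± 0.171 CPM in Etv5KO, none past the threshold. The ciliated list had a camera adjusted p of 0.0284, and an adjusted p of 0.546 with an estimated correlation. Leaving out single libraries ended the calls of Hp (AT2_Etv5KO 1, 4 or 5 or AT2_control 4, adjusted p up to 0.0564), Dynlrb2 (AT2_Etv5KO 1, 3 or 4 or AT2_control 4, up to 0.0690), Muc5b (AT2_control 1 or 4, up to 0.0600) and the ciliated list (AT2_Etv5KO 3 or AT2_control 2 or 4, up to 0.108).

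Most markers of non-epithelial cells were lower in control AT2 cells than in control lung. Among 16 endothelial markers, Car4 rose from 3.10 ± 0.445 to 5.57 ± 0.931 CPM and Esam, the most abundant, fell from 174 ± 11.3 to 145 ± 2.64 CPM, with the same counts adjusted over the list alone. Cdh5 and Calcrl, the next most abundant, stood at 23.6 ± 3.99 CPM in controls and 27.4 ± 5.87 CPM in Etv5KO and at 21.1 ± 3.32 CPM in controls and 24.6 ± 5.59 CPM in Etv5KO. Among 8 lymphocyte markers, Ly6d rose from 2.49 ± 0.772 to 5.75 ± 1.32 CPM, and 3 rose adjusted over the list alone. Cd79b stood at 28.3 ± 6.93 CPM in controls and 39.5 ± 4.8 CPM in Etv5KO and Cd79a at 0.771 ± 0.198 CPM in controls and 1.10 ± 0.373 CPM in Etv5KO. The 13 mesenchymal markers did not pass singly with edgeR, DESeq2 or limma-voom, and 4 were higher at an unadjusted p under 0.05. The 3 most abundant were the collagen genes Col3a1 (16.3 ± 5.05 CPM in controls and 21.9 ± 7.23 CPM in Etv5KO), Col1a2 (10.6 ± 4.05 CPM in controls and 14.8 ± 4.54 CPM in Etv5KO) and Col1a1 (10.3 ± 3.27 CPM in controls and 13.8 ± 4.74 CPM in Etv5KO). By camera, the endothelial, lymphocyte and mesenchymal lists were higher (adjusted p 0.0216, 0.00611 and 0.0152), with adjusted p of 0.614, 0.546 and 0.546 with an estimated correlation. Of 14 macrophage markers, Cd68 rose from 16.2 ± 3.57 to 25.3 ± 1.81 CPM and Cd14 fell from 55.8 ± 9.81 to 25.9 ± 7.25 CPM, or 1 and 2 adjusted over the list alone (camera adjusted p 0.945). The neutrophil list (0.945) and the 1 basal marker tested, Krt15 (0.827), did not pass, and the red blood cell genes did not reach the count filter. The macrophage list had a median of 0.03 and a mean of −0.05. Cd14 was higher in control AT2 cells than in control lung, so its fall alone does not mark macrophages here. The neutrophil list had a median of 0.09, and a mean of −0.01 with a test towards lower values. Calls were lost for Esam without AT2_control 3 (adjusted p 0.0620), for the endothelial list without AT2_Etv5KO 3 or 5 or AT2_control 2 or 4 (up to 0.107) and for the mesenchymal list without AT2_Etv5KO 2 or 5 or AT2_control 3 (up to 0.0776). Cd79b passed without AT2_Etv5KO 2 or AT2_control 3 (down to 0.0259).

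**Figure D2:**
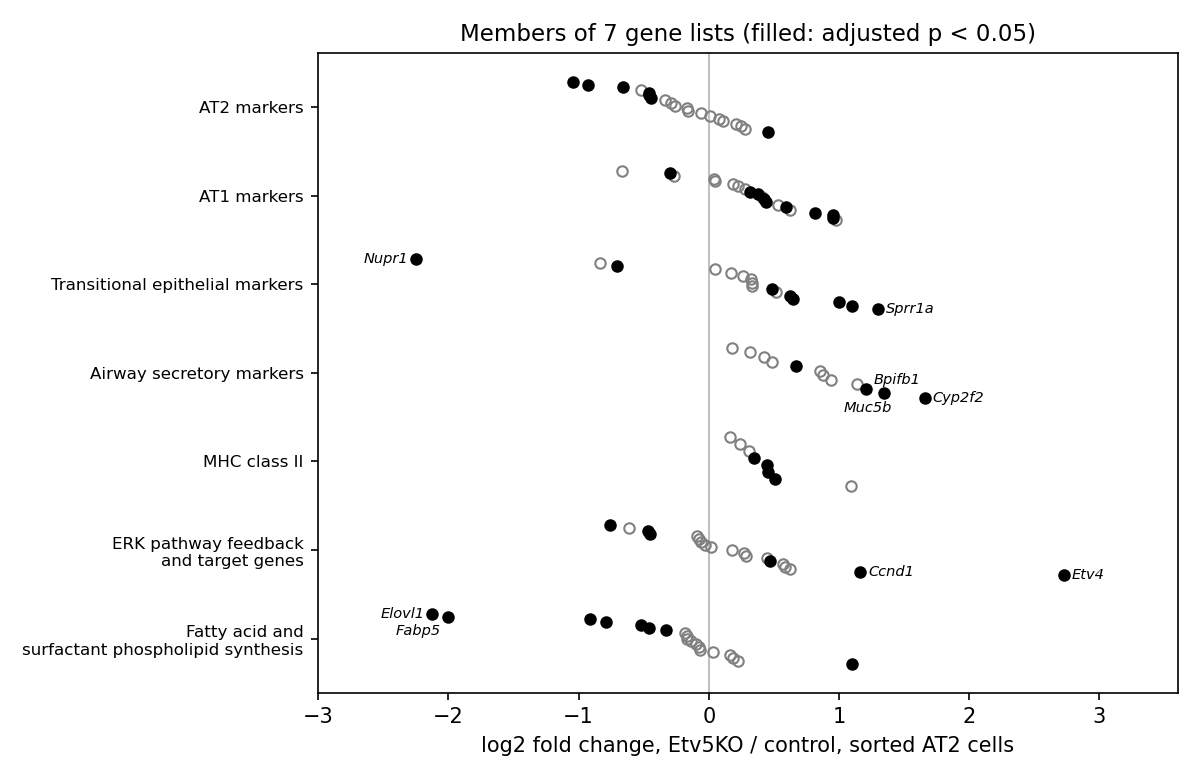
Log2 fold change (Etv5KO over control, sorted AT2 cells) of each tested member of 7 gene lists, with genes past an edgeR adjusted p of 0.05 filled and the others open. Members of the AT2 marker and lipid synthesis lists lie on both sides of 0, down to −1.04 for Chil1 and −2.12 for Elovl1, and the 12 airway secretory and 8 MHC class II members lie above 0 under each scaling tried.

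Genes of the antigen-presenting MHC class II pathway were higher as a list by camera (adjusted p = 4.1e-05). The adjusted p was 0.546 with an estimated correlation and 0.0236 by fry. Of 8 members, 4 rose and 4 did not pass, or 7 rose adjusted over the list alone. Cd74, the invariant chain, went from 4299 ± 243 to 5868 ± 343 CPM, H2-Aa from 970.4 ± 61.9 to 1332 ± 129 CPM, H2-Ab1 from 580.0 ± 29.4 to 826 ± 96.4 CPM and H2-Eb1 from 398 ± 31.5 to 508 ± 43.4 CPM. The call of H2-Eb1 was lost without AT2_Etv5KO 1, 4 or 5 or AT2_control 1, 3 or 4 (adjusted p up to 0.0620).

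The ERK pathway feedback and target genes did not pass as a group (camera adjusted p = 0.152). Of 19 members, 3 rose and 3 fell, or 7 and 3 adjusted over the list alone. Etv4, a close relative of Etv5, rose from 0.580 ± 0.254 to 3.99 ± 0.919 CPM (6.63-fold), and the cyclin D1 gene Ccnd1 from 453 ± 64.7 to 1015 ± 127 CPM. The feedback inhibitor genes Spry1 and Dusp6 fell from 389 ± 36.4 to 230.2 ± 15 CPM and from 106 ± 7.32 to 77.3 ± 10.8 CPM. Among 22 other ETS family genes, 2 rose and 1 fell, over all genes and adjusted over the list alone. They were Elk3 (1.83-fold), Etv4, and Ehf, which fell from 168 ± 4.88 to 139 ± 13.9 CPM. The ETS list had an adjusted p of 0.0570 by camera and 0.0499 by fry, and passed by camera without AT2_Etv5KO 4 or AT2_control 2 (down to 0.0147). The call of Ehf was lost without AT2_Etv5KO 2, 3, 4 or 5 or AT2_control 1, 3 or 4 (adjusted p up to 0.117).

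Among the remaining lists in AT2 cells, the immediate early and dissociation response was lower by camera (adjusted p = 0.00611, and an adjusted p of 0.546 with an estimated correlation). Of its 14 members, Jun fell from 2282 ± 446 to 1653 ± 138 CPM and 13 did not pass, or 3 fell adjusted over the list alone. YAP and TEAD targets were higher (camera adjusted p = 0.0126, and an adjusted p of 0.546 with an estimated correlation), with Crim1 (2.11-fold) and Nuak2 (1.53-fold) higher out of 12, or 3 adjusted over the list alone. The cell cycle list was higher by camera (adjusted p = 0.00447, and an adjusted p of 0.614 with an estimated correlation). Its single member past the threshold, over all 20 and adjusted over the list alone, was the mitotic checkpoint kinase gene Bub1, which fell from 31.5 ± 2.58 to 9.56 ± 3.09 CPM. Mki67 and Top2a, markers of dividing cells, stood at 48.8 ± 39.8 CPM in controls and 90.2 ± 36.9 CPM in Etv5KO and at 41.2 ± 32.7 CPM in controls and 74.0 ± 35.2 CPM in Etv5KO and did not pass. Calls were lost without AT2_control 4 for the immediate early list (0.0883) and the cell cycle list (0.0696), without AT2_control 3 for the YAP list (0.0551), and for Jun without AT2_Etv5KO 1, 2, 3 or 5 or AT2_control 4 (up to 0.0831).

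The other lists did not pass by camera in AT2 cells. The adjusted p was 0.113 for WNT targets, 0.112 for unfolded protein and amino acid stress, 0.153 for p53 targets, 0.252 for epithelial identity, 0.363 for interferon response, 0.382 for chemokines, 0.504 for NRF2 response, 0.807 for TGF-beta response and 0.940 for lysosome and lamellar body. The TGF-beta list had a median of 0.06 and a mean of −0.02. Members went both ways in epithelial identity (of 12, 2 rose and 2 fell), NRF2 response (of 14, 2 rose and 3 fell), and TGF-beta response and lysosome (1 rose and 1 fell in each). Without AT2_Etv5KO 1 the WNT list passed (0.0323), and without AT2_Etv5KO 3 or AT2_control 2 the stress list (down to 0.0270). In all, 13 of 28 lists passed by camera, 8 without AT2_control 4. Other splits of the AT2 libraries into groups of the same sizes gave a median of 8 lists, so the camera p-values are descriptive. Library AT2_control 2 stood apart from the other AT2 controls on the second principal component, with a score of −41.1 where the others lay between −1.69 and 8.18. Without it the ciliated and endothelial lists did not pass (adjusted p 0.107 each), and the ETS family (0.0147) and stress (0.0270) lists did. With an estimated correlation the adjusted p was 0.263 or more, with 1 list at an unadjusted p under 0.05, and 3 lists passed by fry.

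In whole lung, the largest changes in the libraries labelled Etv5KO, among genes with a mean of at least 5 CPM, were falls of Bex2, Acoxl, Nrn1 and Trpv6. Bex2 went from 25.4 ± 4.41 to 3.89 ± 1.56 CPM (log2 −2.71, SE 0.24) and Acoxl from 119 ± 16.5 to 19.4 ± 6.26 CPM (log2 −2.62, SE 0.20). Nrn1, which encodes neuritin, went from 18.3 ± 4.69 to 3.25 ± 0.835 CPM and Trpv6 from 8.67 ± 2.01 to 2.00 ± 0.555 CPM. Elovl1 (from 425 ± 77.8 to 183 ± 11.1 CPM), the acyl-CoA thioesterase gene Acot7 (from 128 ± 16.8 to 54.4 ± 6.68 CPM), Fabp5, Galnt13, Lcn2 and the macrophage receptor gene Marco were the other large falls. Among the rises, the peptide transporter gene Slc15a1 went from 3.99 ± 0.501 to 12.8 ± 1.80 CPM, the anion exchanger gene Slc26a4 from 5.10 ± 2.26 to 20.2 ± 9.53 CPM, Lgi2 from 14.6 ± 2.60 to 31.9 ± 3.34 CPM and Gpam from 203 ± 19 to 387 ± 15.4 CPM. Mfsd2a, S100a14, Bcan, Dgkg, Sema4f and Steap2 rose 2.49-fold, 2.28-fold, 2.16-fold, 2.02-fold, 1.84-fold and 1.69-fold. Each group had 5 libraries. For these 20 genes all Etv5KO libraries lay on the same side of all controls, which the rule for naming them required. The calls of 5 of them were lost without single libraries. These were Slc26a4 (lung_Etv5KO 2, 4 or 5 or lung_control 2, 3, 4 or 5, adjusted p up to 0.105), Mfsd2a (lung_Etv5KO 1, 2 or 4 or lung_control 1, 2, 4 or 5, up to 0.101) and Steap2 (lung_Etv5KO 1, 2, 4 or 5 or lung_control 2 or 4, up to 0.0939). The others were Lcn2 (lung_Etv5KO 1, 2, 3 or 5 or lung_control 2 or 4, up to 0.0702) and Marco (lung_Etv5KO 3 or 5 or lung_control 3, up to 0.0563).

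In all, 71 of 17098 genes passed in lung with edgeR, 35 higher and 36 lower, with 15 and 17 changed by at least 2-fold. For all 71 the groups' libraries did not overlap. Over all genes tested the share was 1.55%, against 0.794% by chance. The count fell to 44 without lung_control 4 and 47 without lung_control 3, and was 192 with DESeq2, 122 in a fit of all 19 libraries and 35 in a test against a fold change of 1.2.

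Few members of the fixed lists passed in lung. Of 20 AT2 markers, Sftpa1 fell from 5157 ± 654 to 3005 ± 479 CPM and Dram1 from 508 ± 33.8 to 380.5 ± 32.1 CPM, or 6 fell and 4 rose adjusted over the list alone, and the list did not pass (camera adjusted p = 0.118). Chil1 stood at 834 ± 103 CPM in controls and 461 ± 123 CPM in Etv5KO and Cxcl15 at 1964 ± 142 CPM in controls and 1329 ± 212 CPM in Etv5KO. Neither passed in the main edgeR fit, but each did in 6 of the alternatives, fits with 1 library left out included. Of 20 lipid synthesis genes, Gpam rose and Elovl1 and Fabp5 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.103). The calls of Sftpa1 and Dram1 were lost without lung_Etv5KO 1, 2, 3 or 5 or lung_control 2, 3, 4 or 5 (adjusted p up to 0.102 and 0.121). Chil1 passed without lung_Etv5KO 2 or 4 (down to 0.0423), Cxcl15 without lung_Etv5KO 4 (0.0229), and the AT2 marker list without lung_Etv5KO 4 (0.0136).

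The MHC class II list had the lowest camera adjusted p in lung, 4.54e-08, and was higher. With an estimated correlation its adjusted p was 0.578. Its 8 members did not pass singly with edgeR or limma-voom over all genes; 6 rose adjusted over the list alone, 6 were higher at an unadjusted p under 0.05 and 2 passed with DESeq2. Cd74 stood at 1755 ± 246 CPM in controls and 2376 ± 274 CPM in Etv5KO and H2-Aa at 508 ± 71.0 CPM in controls and 677 ± 71.8 CPM in Etv5KO. Cholesterol synthesis (8.24e-06; Nsdhl at 22.5 ± 3.61 CPM in controls and 28.5 ± 2.84 CPM in Etv5KO) and cell cycle genes (0.000410; Mcm6 at 46.3 ± 11 CPM in controls and 53.2 ± 5.46 CPM in Etv5KO) were also higher by camera, each with an adjusted p of 0.601 with an estimated correlation. So were epithelial identity (0.00142; Nkx2-1, a transcription factor of lung epithelium, at 209 ± 9.40 CPM in controls and 255 ± 16.8 CPM in Etv5KO) and interferon response (0.00881), each also with 0.601 with an estimated correlation. The NRF2 response list was lower (0.0226, and an adjusted p of 0.578 with an estimated correlation). Gclc, of the NRF2 list, stood at 198 ± 26.6 CPM in controls and 312 ± 56.5 CPM in Etv5KO. Adjusted over the list alone Gclc rose, as did 3 epithelial identity genes. Camera calls were lost without single libraries for epithelial identity (lung_control 1, adjusted p 0.109), interferon response (lung_Etv5KO 2 or lung_control 3, up to 0.526) and NRF2 response (lung_Etv5KO 1 or 3 or lung_control 4, up to 0.0754).

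Several lists of cell type markers also passed in lung by camera, each with an adjusted p of 0.601 with an estimated correlation. AT1 markers were higher (0.00168), with Ager at 1815 ± 94.8 CPM in controls and 2199.9 ± 275 CPM in Etv5KO, Emp2 at 1542 ± 69.9 CPM in controls and 1689 ± 139 CPM in Etv5KO and Ahnak at 1436 ± 395 CPM in controls and 1402 ± 288 CPM in Etv5KO. Transitional epithelial markers were higher (0.0222), with Fn1 at 486 ± 205 CPM in controls and 568 ± 158 CPM in Etv5KO, Krt7 at 264 ± 29.2 CPM in controls and 299 ± 31.9 CPM in Etv5KO and Clu at 224 ± 20.7 CPM in controls and 209 ± 20.3 CPM in Etv5KO. Nupr1 fell from 79.7 ± 7.01 to 56.6 ± 5.15 CPM, and adjusted over the list alone 3 rose and 1 fell. Mesenchymal markers were higher (0.0426), with Col3a1 at 1142 ± 495 CPM in controls and 1439 ± 452 CPM in Etv5KO, Inmt at 928 ± 252 CPM in controls and 1003 ± 277 CPM in Etv5KO and Eln at 844 ± 629.9 CPM in controls and 799.9 ± 259 CPM in Etv5KO. Endothelial markers were lower (0.0222), with Calcrl at 1584 ± 233 CPM in controls and 1400.4 ± 238 CPM in Etv5KO, Cdh5 at 1446 ± 79.3 CPM in controls and 1309 ± 157 CPM in Etv5KO and Pecam1 at 1076 ± 108 CPM in controls and 1008 ± 133 CPM in Etv5KO. Macrophage markers were lower (0.0477), with Chil3 at 558 ± 121 CPM in controls and 479.7 ± 121 CPM in Etv5KO, Ptprc at 284 ± 58.9 CPM in controls and 254 ± 57.9 CPM in Etv5KO and Csf1r at 259.8 ± 88.7 CPM in controls and 215 ± 34.4 CPM in Etv5KO. Marco fell (log2 −1.29), a call lost without lung_Etv5KO 3 or 5 or lung_control 3 (adjusted p up to 0.0563). With an estimated correlation 2 of the 29 lists in lung had an unadjusted p under 0.05, by fry the lowest adjusted p was 0.324, and 7 lists passed by camera without lung_Etv5KO 2. By camera 11 lists passed, and other splits of the lung libraries gave a median of 9, so these camera p-values are also descriptive. Camera calls were lost without single libraries for AT1 markers (lung_Etv5KO 5, adjusted p 0.137), transitional epithelial markers (lung_Etv5KO 2 or lung_control 2, up to 0.0693), mesenchymal markers (lung_Etv5KO 1, 2, 3 or 5 or lung_control 2, 4 or 5, up to 0.206), endothelial markers (lung_Etv5KO 2 or 3 or lung_control 4 or 5, up to 0.381) and macrophage markers (lung_Etv5KO 1 or 3 or lung_control 1 or 4, up to 0.850). The call of Nupr1 was lost without lung_Etv5KO 3 or lung_control 2, 3, 4 or 5 (up to 0.0605).

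The other 18 lists in lung did not pass by camera, the AT2 marker and lipid synthesis lists included. The adjusted p was 0.0635 for lysosome and lamellar body, where the cholesterol carrier gene Npc2 rose from 1030.0 ± 85.4 to 1483 ± 153 CPM, 0.103 for neutrophil, 0.118 for ciliated, 0.133 for ETS family and for YAP and TEAD targets, 0.194 for red blood cell, 0.262 for p53 and 0.266 for WNT. It was 0.284 for ERK pathway, basal and unfolded protein and amino acid stress genes, 0.409 for airway secretory and immediate early genes, 0.438 for chemokine, 0.762 for lymphocyte and 0.956 for TGF-beta genes. The red blood cell and TGF-beta lists had a negative median (−0.13 and −0.04) and mean (−0.12 and −0.01) where camera gave a higher direction. Lists that passed without single libraries were lysosome (lung_Etv5KO 3 or lung_control 1 or 3, down to 0.0171), neutrophil (lung_Etv5KO 3 or 4 or lung_control 3, down to 0.00510), red blood cell (lung_control 4 or 5, down to 0.00980), lymphocyte (lung_Etv5KO 1, 0.00325), ETS family (lung_Etv5KO 4, 0.0486), unfolded protein and amino acid stress (lung_control 2, 0.0395) and YAP and TEAD targets (lung_Etv5KO 5, 0.0290). Library lung_control 1 stood apart from the other controls on the first principal component, with a score of 29.4 where the others lay between −21.3 and −10.4. Without it the airway secretory (0.0256), ciliated (7.65e-05) and lipid synthesis (0.0224) lists passed.

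Genes that passed in both tissues moved the same way. Acoxl, Bex2, Trpv6, Elovl1, Fabp5, Acot7, Nrn1 and Hes2 fell in both, and Gpam, Dgkg, S100a14, Slc15a1 and Myom2 rose in both. Among 14550 genes tested in both, 30 were higher in both, where 1.64 would be shared by independent lists, and 35 were lower in both, where 1.73 would be (two-sided Fisher's exact test, p = 2.14e-36 and 1.03e-45). The shared count of 65 was 166 with DESeq2, and at an unadjusted p under 0.05 in edgeR 563 genes moved the same way in both and 9 in opposite directions. Of 724 genes higher in AT2 cells, 588 also had a positive log2 fold change in lung, and of 698 lower genes 601 had a negative value. Their median in lung was 0.15 and −0.14, against 0.55 and −0.63 in AT2 cells. AT2 and lung libraries may come from the same mice, so these comparisons are not independent.

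The genotype difference was compared between the tissues with an interaction term, to show where the log2 fold change differed between sorted AT2 cells and whole lung. Whole lung holds AT2 cells among other cells. Where other lung cells express a gene, such a difference can arise although the AT2 cells change alike in both. The term does not separate this from an effect that depends on the tissue. Trf fell from 758 ± 136 to 57.1 ± 11.9 CPM in AT2 cells and stood at 442 ± 36.0 and 369 ± 24.6 CPM in lung, a difference of log2 fold changes of −3.47 (SE 0.18). Adamts1, Rbp4, Tgfbi and Gdpd2 had differences of −4.10, −4.04, −2.92 and −2.59. In the other direction, Angpt2 rose from 1.91 ± 0.674 to 13.7 ± 2.11 CPM in AT2 cells and stood at 30.1 ± 8.60 and 29.8 ± 4.97 CPM in lung (difference 2.88, SE 0.30). Cyp1b1, the calcium pump gene Atp2b2, Ccdc88b and Rapgef4 had differences of 2.71, 2.44, 2.40 and 2.39. In all, 282 of 17698 genes passed with edgeR, 140 with a more positive log2 fold change in AT2 cells and 142 with a more negative one. The count was 455 with DESeq2, and Atp2b2 lost its call with limma-voom.

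Control AT2 cells were compared with control lung to show what the sort enriched. All 20 AT2 markers were higher in the sorted cells, with Sftpc at 78102 ± 17716 against 8092 ± 1095 CPM and Etv5 at 664 ± 35.9 against 103 ± 7.12 CPM (6.45-fold). All 20 cholesterol synthesis genes, 12 of 12 epithelial identity genes and 16 of 20 lipid synthesis genes were also higher. All 16 endothelial and 14 mesenchymal markers and 13 of 14 macrophage markers were lower, with Pecam1 at 20 ± 3.33 against 943 ± 91.5 CPM. Of 20 AT1 markers 3 were higher, or 1 with the scaling that gave the fewest, and 15 were lower. Of 11 airway secretory markers 5 were higher and 5 lower. Immediate early genes, which respond to cell dissociation, were higher in all 14 members, or 13 with library size only. Fos stood at 3814 ± 695 against 26.0 ± 4.51 CPM, Fosb at 2341 ± 365 against 6.06 ± 2.40 CPM and Egr1 at 2077 ± 512 against 37.3 ± 17.8 CPM. Values are means ± SD over 4 AT2 and 5 lung libraries.

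Iqcn (80.7 ± 23.9 against 0.179 ± 0.0768 CPM) and Fam71a were the other largest rises. Fam71a had no read in the 5 lung controls and 16 CPM in AT2 cells on average, at least 626-fold higher against a floor of 3 counts over the lung group. Haemoglobin genes were the largest falls: Hbb-bs and Hbb-b1, whose counts are identical, had 41332 reads in lung and 16 in AT2 cells, Hba-a1 14187 and 5, and Hbb-bt and Hbb-b2, also identical, 9458 and 2. For AT2 versus lung in controls, 12754 of 17118 genes passed with edgeR, 6092 higher and 6662 lower. With library size as the only scaling, the split was 3318 higher and 9484 lower, and the median log2 fold change of all genes moved from −0.01 to −0.42.

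Genes next to Etv5 on its chromosome were looked at after their values had been seen. Dgkg, a diacylglycerol kinase gene and the nearest tested gene on the promoter side of Etv5, rose in AT2 cells (log2 1.33, SE 0.14) and in lung (1.01, SE 0.11). 9230117E06Rik, which lies inside Dgkg on the other strand, rose by 1.57 (SE 0.15) and 1.68 (SE 0.16). Whether the counting used strand is not given in the sources used here, so the reads of this pair cannot be told apart. Tra2b, the first tested gene on the other side of Etv5, did not pass in either tissue (−0.02 in AT2 cells and −0.01 in lung). Among the 51 genes from 25 places before Etv5 to 25 after it, 12 passed in AT2 cells, 5 higher and 7 lower, and 2 in lung.

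**Figure D3:**
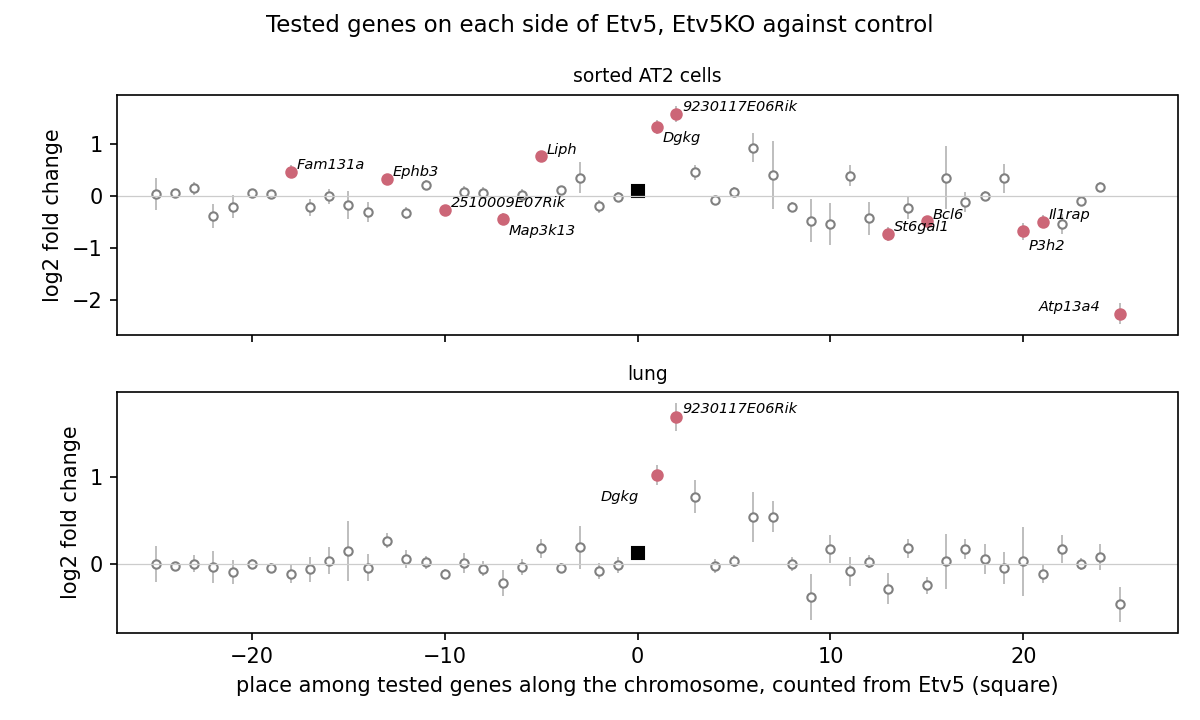
Log2 fold change (Etv5KO over control) with its standard error of the 25 tested genes on each side of Etv5, in the order of assembly GRCm38.p6, in AT2 cells (top) and lung (bottom). Filled points passed an edgeR adjusted p of 0.05 and the square is Etv5; Dgkg and 9230117E06Rik, at places 1 and 2, passed in both.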

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

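The tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the libraries, which were planned. The highest or lowest library of each group was compared with the others for 136 genes named for the genotype comparisons and the difference between tissues. The genes named for control AT2 cells against lung, total counts, genes with a read and the share of counts in the 10 most abundant genes were added. Of these 372 groups of values chance alone would set apart about 1 in 20, or 18.6, and 32 were found. Values for genes are in CPM scaled over all 19 libraries.

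Library lung_control 1 held 7 of the 32. It had the highest Col3a1 (1784), Adamts1 (207), Mcm5 (38.1) and Slc7a11 (15.7) of the 5 lung controls. It had the lowest Cyp2f2 (1126) and Scgb1a1 (12368), and the lowest share in the 10 most abundant genes (5.22%). Among the other lung controls, lung_control 4 had the highest Acot7 (139), Aqp5 (264) and Cxcl15 (1964), and lung_control 3 the highest Chil3 (679). Among lung Etv5KO libraries, lung_Etv5KO 2 had the highest Lum (19.4), Dcn (305) and Mcm6 (55.6), and lung_Etv5KO 1 the highest Atp2b2 (12.2) and the lowest Csf1r (138) and Slc7a11 (1.59). The lowest Etv5 (94.4) and Trf (327) were in lung_Etv5KO 3 and the highest Dgkg (25.9) in lung_Etv5KO 4.

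In AT2 cells, AT2_control 2 had the lowest Sftpa1 (25610.3) of the controls and the highest Hbb-bs and Hbb-b1 (0.292 each, from identical counts), and AT2_control 4 had the highest Jun (3373) and Fam71a (22.9). Of the Etv5KO libraries, AT2_Etv5KO 1 had the highest Hes2 (1.71) and Dcn (10.6), AT2_Etv5KO 2 the highest Ccdc88b (14.8), and AT2_Etv5KO 3 the highest Ncf1 (121) and the lowest Entpd3 (25.4), Tgfbi (7.65) and Esam (161).

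For 30 named genes the difference between Etv5KO and control itself differed between AT2 cells and lung by the interaction term. Such a difference can arise with the same change in the AT2 cells of lung, where other lung cells express the gene. The log2 fold change was more negative in AT2 cells, by AT2 minus lung, for Adamts1 −4.10, Rbp4 −4.04, Trf −3.47, Tgfbi −2.92, Gdpd2 −2.59, Ppp1r3c −2.29, Nupr1 −1.77, Elovl1 −0.92, Acot7 −0.72, Clu −0.61 and Spry1 −0.51. It was more positive for Angpt2 2.88, Cyp1b1 2.71, Atp2b2 2.44, Ccdc88b 2.40, Rapgef4 2.39, Etv4 2.20, Ncf1 1.98, Cyp2f2 1.95, Rasl12 1.80, Emp1 1.79, Entpd3 1.59, Ano1 1.48, Crim1 1.25, S100a14 1.01, Elk3 0.90, Clic5 0.87, Lgals3 0.85, Ccnd1 0.74 and Emp2 0.45.

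Etv5 was not lower in the libraries labelled Etv5KO. Swapped or wrong labels of single libraries were tested by scoring AT2 libraries on the genes called in lung and lung libraries on those called in AT2 cells: the genotypes were apart in both, with a gap of 1.98 on the log2 scale in AT2 cells and 0.273 in lung, so no library lay among the other genotype. If most sorted cells had kept an intact loxP allele and behaved like controls, no gene could fall below a fold of 0.5, yet 51 of 10647 genes had their upper 95% bound below it (a first count, 805 below the lower bound of Etv5, was replaced); such cells still carry the knockout allele, and no library has that allele alone, so it cannot be told apart. Reads from the part of the gene that a deletion leaves in place cannot be told apart from whole transcripts in counts over the gene (log2 0.10 in AT2 cells), so this explanation stays open. Effects of the single knockout allele, which lung cells other than AT2 cells also carry, were not tested.

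AT1 and airway markers were higher in the AT2 libraries labelled Etv5KO by camera, where 8 of 20 and 4 of 12 rose and Aqp5 fell, with list adjusted p of 0.263 and 0.546 with an estimated correlation. If airway secretory cells had brought the Cyp2f2 rise, Scgb1a1 would need a log2 fold change of 2.87 by its ratio to Cyp2f2 in control lung, while its upper 95% bound was 0.81. If whole-lung levels stand for the profile of AT1 cells, which was not measured, AT1 cells in the sort would raise all AT1 markers by the same share of their lung level. Of the AT1 markers, 5 rose from at least 4 times below their lung level. The share needed by 4 of them (Clic5, Timp3, Ahnak and Akap5) lay above the upper bounds of most markers held at under 10% of it (5 to 7 of 7 or 8). Under that assumption this argues against AT1 cells for these 4. The share needed by Cav1 lay above 1 of 7, so for Cav1 AT1 cells and a lower share of AT2 cells cannot be told apart from a change within AT2 cells. A lower share of AT2 cells is argued against in the same way for 5 markers, these 4 and Cyp2f2. Bpifb1 did not reach the count filter in lung. Ager, Emp2, Gprc5a, Hp and Muc5b are too high in control AT2 cells, against lung, for this test. It replaced, after their values were seen, airway minus macrophage scores (0.702, exact permutation p = 0.0159, n = 4 and 5), mesenchymal minus macrophage scores (0.360, p = 0.175) and needs taken from Ager, which control AT2 cells hold above its lung level; a change of the AT2 cells themselves remains a hypothesis.

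Genes past the threshold lay close to Etv5 on its chromosome. In AT2 cells 12 of the 51 genes in the window, Etv5 included, passed (23.5%, against 10.1% of all placed genes), and 1.36% of all windows of 51 genes held as many, or 3.16% held 11 or more with Dgkg and 9230117E06Rik, whose reads cannot be separated, taken as 1. In lung this pair alone passed, so its 2 calls may be 1 signal, and 18.8% of windows held at least 1. Transcripts running past the 3' end of Etv5 cannot reach its promoter side, which holds 7 of the 12 calls, and Dgkg there rose with a lower 95% bound of 1.02. Of the 5 calls beyond the 3' end, Map3k13 (log2 −0.45, SE 0.11) and 2510009E07Rik (−0.27, SE 0.08) fell. Reads added by such transcripts cannot lower a count, which argues against them for these genes. For Fam131a, Ephb3 and Liph, which rose, they cannot be told apart, since the upper bound of Tra2b (0.18) leaves room for a small rise. A first count of lower neighbours (7 of 12) was dropped. Strain DNA carried along with the knockout or loxP allele, and an effect of the deletion on nearby regulation, were not tested and stay open.

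Other splits of the libraries into groups of the same sizes, 100 for each comparison with the real one included, were used to ask whether chance can be excluded. For AT2 cells chance alone is unlikely: 1 split, the real one, gave 1474 genes, and the highest other gave 13. The same holds for control AT2 cells against control lung (1 split, 12754 genes, highest other 4865) and for the difference between the tissues (1 split, 282 genes, highest other 104). With 100 splits a share below 1 in 100 cannot be seen. The splits also take the libraries as separate mice, which no label says in words. In lung 2 of the 100 splits gave at least the real count of 71, the real one and another with 341 genes. A count as large as the real one was thus rare among the splits. Since a grouping other than the genotypes exceeded it, the number of genes alone does not exclude chance in lung. The split with 341 genes exchanges lung_control 1 and lung_Etv5KO 4. It divides the lung libraries by their score on the first principal component (24.2% of the variance), between lung_Etv5KO 4 (−4.91) and lung_Etv5KO 1 (−3.12). This split thus follows the main axis of variation in lung, which is not the genotype. What lies behind that axis was not tested. Chance cannot be excluded for the number of gene lists past the threshold: 9 splits gave at least 13 in AT2 cells (highest other 19) and 28 gave at least 11 in lung (highest other 17). The median of the other splits was 8 lists in AT2 cells and 9 in lung. A lung fit without that pair of libraries called more genes and is not reported, because the pair was picked by the outcome.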

How the results depend on the processing

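No test of an explanation is reported in this part; the authors' size factors and a fit without AT2_control 2 and lung_control 1, which stand apart, were tried after the data were seen. No named gene past its threshold changed direction under the alternatives that were run. The count for AT2 Etv5KO versus control, 1474, ranged from 1205 to 1994 over other scalings, tests, filters and covariates, was 624 against a fold change of 1.2, and ranged from 1062 (without AT2_control 3) to 1587 (without AT2_control 2) with 1 library left out. The lung count of 71 was 192 with DESeq2, 122 with all 19 libraries in 1 fit and 35 against a fold change of 1.2, and ranged from 44 (without lung_control 4; 47 without lung_control 3) to 80 (without lung_control 1). The count for control AT2 cells against lung ranged from 12038 to 12986 and that for the difference between tissues from 198 to 319 with 1 library left out; the latter was 455 with DESeq2. The 65 genes shared by both tissues were 166 with DESeq2, 32 at an adjusted p under 0.01 and 73 without AT2_control 2 and lung_control 1.

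The number of lists past the threshold in AT2 cells, 13 of 28 by camera, was 0 with the correlation estimated (1 at an unadjusted p under 0.05), 3 by fry and 11 without genes shared between lists, and lay between 8 (without AT2_control 4) and 14 (without AT2_Etv5KO 1) with 1 library left out. The number in lung, 11 of 29 by camera, was 0 with the correlation estimated (2 at an unadjusted p under 0.05), 0 by fry (2 unadjusted) and 9 without shared genes, and lay between 7 (without lung_Etv5KO 2) and 14 (without lung_Etv5KO 4). Etv5 stayed between 0.07 and 0.16 in AT2 cells and 0.08 and 0.18 in lung (log2) over all alternatives, including those with 1 library left out, and did not pass. A test against a larger fold is stricter by construction, and fewer libraries give less precision; the cause of the other changes was not tested.

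Among named genes, the test against a fold change of 1.2 ended the AT2 calls of Dram1, Cxcl15, Gprc5a, Hp, Dynlrb2, Esam, Acss2, H2-Ab1, H2-Aa, Cd74, H2-Eb1, Jun, Nuak2, Dusp6 and Ehf and the lung calls of Slc26a4, Mfsd2a, Steap2, Lcn2, Nupr1, Sftpa1 and Dram1. A single fit of all libraries ended those of Bpifb1, Muc5b and Ehf in AT2 cells and Nupr1 in lung, and library size only those of Esam, Jun, Dusp6 and Ehf. Ehf was also lost with the authors' factors, without a filter and with the most abundant genes left out. In lung, limma-voom ended the calls of Slc26a4 and Mfsd2a, sample weights that of Mfsd2a, and the surrogate variable and the authors' factors that of Dram1. In the tests with 1 library left out, 669 of the AT2 values kept their side of the threshold, 29 were no longer past it and 9 newly past it; in lung these were 726, 50 and 4.

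No paired analysis was possible because the labels do not say which AT2 and lung libraries came from the same mouse. A covariate for sex was not run, since Xist was at most 3.10 CPM in every library and Y-linked genes were expressed. Other pseudocounts were not run: the edgeR tests used counts, and the prior count of 2 behind the list tests was not varied. In simulated counts, 80% of 1.5-fold changes in genes with a mean of at least 5 CPM were recovered in AT2 cells and 77% in lung. For the difference between tissues 28% were, which limits what that comparison can show.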

Other observations

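The tests of this part were planned, while the genes named in its first paragraph were chosen after their values were seen. Further genes changed in the same direction in both tissues. Cebpa, a transcription factor of AT2 cell maturation, fell from 763 ± 96.7 to 445 ± 90.2 CPM in AT2 cells and from 211 ± 17.8 to 145 ± 20.1 CPM in lung. Arg2, the mitochondrial arginase, fell from 33.6 ± 8.42 to 8.03 ± 0.424 CPM and from 8.13 ± 1.21 to 4.15 ± 1.01 CPM, with a larger fall in AT2 cells (difference −1.10, edgeR adjusted p 0.0109). The peptidase gene Anpep had log2 fold changes of −0.82 in AT2 cells and −0.69 in lung, the secreted phospholipase gene Pla2g1b of −0.64 and −0.71, and Bex1 of −1.30 and −1.08. Abcd3, a peroxisomal fatty acid transporter gene, rose from 712 ± 48.2 to 1116 ± 69.4 CPM and from 185 ± 12.9 to 271 ± 15 CPM. St3gal5, which makes the ganglioside GM3, rose by 0.96 and 0.50, with a larger rise in AT2 cells (difference 0.45, edgeR adjusted p 0.0146). Since lung also holds other cells, the differences of Arg2 and St3gal5 do not show that AT2 cells within lung changed less. Values are means ± SD over 4 control and 5 Etv5KO AT2 libraries and 5 and 5 lung libraries.

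The changes in lung may be carried by the AT2 cells within it. Among genes called in AT2 cells, the 193 at least 4 times higher in control AT2 cells than in lung had a median lung log2 change of 0.56 in the AT2 direction, and 187 of them (96.9%) had the same sign. The 150 at least 4 times lower had a median of 0.08, and 96 of them (64.0%) had the same sign. The medians differed by a permutation test over genes (one-sided, p = 1e-05, the smallest that 100000 permutations can give). Between them, the 1079 genes within 4 times had a median of 0.13. AT2 cells give a larger part of the lung reads of genes that they hold at higher levels. The same order of medians would thus arise if other lung cells changed too. The test therefore does not show that AT2 cells alone carry the lung changes. Genes are not independent replicates, and the knockout allele in other lung cells stays open.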
